A study of Mus musculus with 11 samples.

How the data were processed

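Whole lungs of C57BL/6 mice, 8 weeks old, were profiled by RNA sequencing at day 3 after intratracheal instillation of bleomycin (3 U/kg) or saline in 50 µL at day 0, per the labels. Bleomycin is a DNA-damaging glycopeptide that is widely used to injure the mouse lung. Polyadenylated RNA was captured, dUTP was added during second-strand synthesis, and the libraries were sequenced in pairs on an Illumina NovaSeq, per the labels' protocols. Samples were grouped by their titles into 6 saline and 5 bleomycin libraries. The labels number the samples within each group but do not state that each came from a separate animal, so p-values measure the spread between these samples.

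The authors deposited 1 table for the whole series, with a read count and an FPKM value per gene and library. The submitters' processing notes name HISAT2 2.2.1, HTSeq 2.0.2, FastQC and the mouse genome build GRCm39. The role of each tool, the annotation and the strand setting of the counting are not given in the sources used here. The deposited counts are whole numbers that were not normalized. The deposited FPKM values are counts per kilobase of gene, scaled to the reads of the library. The table held 14700 genes, each with a read in at least 5 libraries. 3 rows had no symbol, and 1 symbol was used by 2 rows. Genes outside the table were not analysed here, among them several abundant neutrophil genes. The reference annotation at hand was of another build than the authors', so no coordinates are given, and it was used only for the GC content and length of genes (found for 99.9% of the genes tested).

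Total counts ranged from 13226339 to 19009284 per library. For a share of the counts of a single library, 95% Wilson intervals were computed, which cover counting error only. Every pair of libraries differed by more than sampling noise, so none was counted as the same library sequenced again. The closest, saline 1 and 4, had a chi-square of 17.3 per degree of freedom (Spearman's rho 0.989). Saline 2 and 3 had 25.4 (rho 0.986), and the next saline pair, 5 and 6, had 105.9. Saline 2 and 4 correlated at 0.843, below the lowest pair of saline with bleomycin (0.860). Whether close libraries shared an animal or batch is not known, and the tests treat the 6 saline libraries as independent.

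The design fixed before the data were examined gave limma on log2 FPKM as the test, or edgeR should the table hold counts. It held counts, so the main test was edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (count minimum of 10), which left 14478 genes. Libraries were scaled by TMM, and bleomycin was compared with saline by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Levels are CPM (counts scaled to a common library size) after TMM scaling, given as mean ± SD over 6 saline and 5 bleomycin libraries. Fold changes are log2 of bleomycin over saline with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the test's F statistic. Plac8 was also tested by an exact two-sided permutation of mean log2(FPKM + 1) over the 462 splits of the libraries into 5 and 6.

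The 39 gene lists were written together with that design. They cover lung cell types, tissues that can be carried along at dissection, and processes that fit bleomycin injury, apoptosis, autophagy or handling. Each was tested against the other genes by camera with its preset correlation of 0.01, by camera with a correlation estimated from the libraries, and by fry, which tests whether the genes of a list move one way and compares them with no other genes. All 3 were adjusted over the 39 lists (limma 3.58.1). The genes named are Plac8, then the 10 largest rises and the 10 largest falls in log2(FPKM + 1). These were taken among genes past the threshold whose 5 bleomycin libraries all lay on one side of all 6 saline libraries in FPKM and whose mean FPKM was at least 1 in the higher group, leaving out predicted genes and receptor segments. The 21 lists described with examples were chosen after the results were seen. For each of them, up to 4 members were eligible, the 3 with the largest change past the threshold and the tested member with the highest mean FPKM.

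Principal components were taken over log2(FPKM + 1) of the 11138 genes with an FPKM of 1 or more in at least 5 libraries.

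Alternatives fixed in the same way were no filter, a stricter filter (FPKM of 5 or more in at least 5 libraries), median-ratio factors, a block by replicate number, each library left out in turn, a threshold of 0.01, an exact rank-sum test per gene, DESeq2 1.42.0, and limma on log2(FPKM + 1). The limma fit was repeated with pseudocounts of 0.1 and 0.01, with values rescaled by median ratios, to TPM or by quantiles, with array weights and with robust variances. Alternatives added after seeing the data were fits without saline libraries 2 and 3, fits without saline libraries 1 and 4, a correction for the trend of each library on GC content (a smoothing spline with 5 degrees of freedom as an offset) with and without saline libraries 2 and 3, and total-count scaling in edgeR.

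The scripts were tested on simulated data, counts drawn for the comparison of 5 with 6 libraries from the real means, library sizes and dispersions. In these, 200 genes were changed, and 20 others were raised 2-fold as a planted list. Recovery is given over the 200. With 14400 genes tested, edgeR recovered 77.3% of the genes changed 4-fold, 33.3% of those changed 2-fold and 2.99% of those changed 1.5-fold, with 3 calls among 14181 unchanged genes. DESeq2 recovered 95.5%, 56.7% and 7.46% over 14478 genes, and 23.8% of its calls were of unchanged genes. The planted list passed camera, as did 1 of the 39 lists with no planted genes. Genes were drawn independently, whereas the estimated correlation of the real lists reached 0.921 (mitochondrially encoded genes). The simulation therefore does not show how often camera passes a list by chance in the real data.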

Results

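RNA was sequenced from whole mouse lungs at day 3 after intratracheal saline (6 libraries) or bleomycin (5 libraries). The title of the series concerns PLAC8, pulmonary fibrosis, apoptosis of alveolar epithelial cells and autophagy. The comparison asks which transcripts differ early after bleomycin. Total counts were 18974582, 13996304, 15255996, 19009284, 14897614 and 13739589 in saline 1 to 6, and 13704749, 14983245, 15881405, 13226339 and 17010616 in bleomycin 1 to 5.

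Transcripts that rose after bleomycin included some alveolar type 1 markers, transitional epithelial markers, p53 targets and lipid synthesis genes. Those that fell included markers of natural killer, T and dendritic cells and some interferon-induced genes. Of 14478 genes tested, 671 rose and 825 fell (1496 in all, 10.3%) by edgeR's quasi-likelihood test, and 778 of these changed at least 2-fold (306 up, 472 down). All 5 bleomycin libraries lay above all 6 saline libraries in TMM-scaled CPM for 578 genes and below them for 639, or for 761 and 362 in the deposited FPKM, and chance gives such a separation for 0.433% of genes. The biological coefficient of variation was 36.5%. The number changed at least 2-fold was 386, 507, 440 and 453 without bleomycin 2, 3, 4 and 5, and limma on log2(FPKM + 1) gave 345 (220 up, 125 down). The count of all changed genes was 557, 765, 627 and 621 without bleomycin 2, 3, 4 and 5, and 863 without saline 1. Without saline 2 and 3, left out after seeing the data, it was 2778, with 1335 up and 1443 down, and with a GC correction it was 946 (386 up, 560 down). Without saline 1 and 4, likewise left out after seeing the data, it was 876 (286 up, 590 down). With total-count scaling 894 genes rose and 380 fell, and limma on log2(FPKM + 1) gave 955 and 306, or 851 and 54 on TPM. DESeq2 called 2864 genes, limma with array weights 7618, edgeR with a replicate block 506, and an exact rank-sum test 0 (3299 at an unadjusted p under 0.05).

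Plac8 (ENSMUSG00000029322), which encodes a small cysteine-rich protein, averaged 125 ± 94.7 CPM (SD, n = 6) in saline and 36.9 ± 10.9 CPM (SD, n = 5) in bleomycin lungs. Its log2 fold change was -1.76 ± 0.535 (SE), with an adjusted p of 0.0558 by edgeR, so the difference did not pass the threshold. The difference in mean log2(FPKM + 1) was -1.14, with an exact two-sided permutation p of 0.121 over 462 splits. Saline 2, 3 and 5 held 240, 223 and 158 CPM, while saline 1, 4 and 6 held 56.8, 34.3 and 35.5 CPM, within or near the bleomycin range of 23.8 to 53.001 CPM. The call was made without saline 4 (adjusted p = 0.0358) and without saline 6 (adjusted p = 0.0269), as well as by DESeq2 (adjusted p = 0.00635), and the adjusted p ranged from 0.00635 to 0.375 over all alternatives. Without saline 2 and 3 the log2 fold change was -0.95 (adjusted p = 0.124), and without saline 1 and 4 it was -2.13 (adjusted p = 0.0237), past the threshold.

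**Figure D1:**
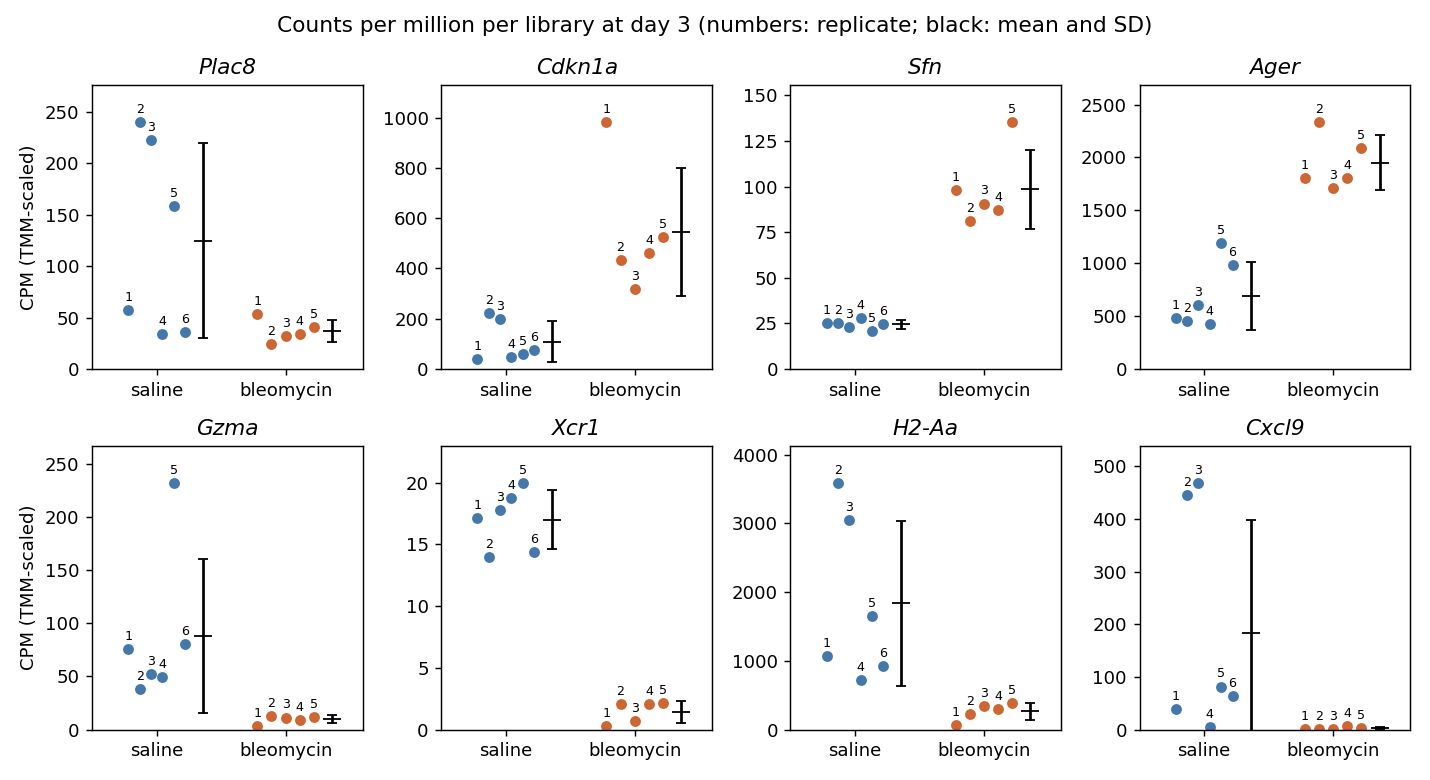
TMM-scaled CPM (vertical axes, linear from 0) of 8 genes in each saline (blue) and bleomycin (orange) library, numbered by replicate, with the mean and SD in black; the lower end of the SD bar of Cxcl9 in saline is cut off at 0. Plac8 was high in saline 2, 3 and 5, whereas Sfn lay between 20.98 and 27.9 CPM in saline and between 81.1 and 135 CPM in bleomycin libraries.

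Among the genes with the largest rises, Cdkn1a, which encodes the cell cycle inhibitor p21, went from 107 ± 81.4 to 545 ± 256 CPM (log2 fold change 2.34 ± 0.495, adjusted p = 0.0161). Sfn, which encodes 14-3-3 sigma, went from 24.5 ± 2.36 to 98.5 ± 21.6 CPM (2.01 ± 0.149, adjusted p = 0.000148). Scnn1a, the alpha subunit of the epithelial sodium channel, rose 3.54-fold. Serpina3n and Serpina3m, protease inhibitor genes, rose 4.93-fold and 6.57-fold, and reads may be split between members of this multigene family. Spock2, Tmem37, Spry4, Gadd45g and Lrg1 rose 3.76-, 3.86-, 4.71-, 3.43- and 3.08-fold. Each of these 10 genes stayed past the threshold in all 11 fits that left out 1 library, and Serpina3n came closest to losing it (adjusted p = 0.0471). Leaving out saline 2 and 3, the log2 fold changes of Cdkn1a and Serpina3n were 3.29 and 3.20. Leaving out saline 1 and 4, they were 1.98 and 1.99, and Serpina3n lost its call (adjusted p = 0.0517).

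Among the largest falls, the trefoil peptide gene Tff2 went from 34.3 ± 21.4 to 1.03 ± 0.491 CPM (log2 fold change -5.07 ± 0.659, adjusted p = 0.00226). Jchain, which links polymeric immunoglobulins, went from 511 ± 468 to 25.1 ± 18.5 CPM (-4.35 ± 0.761, adjusted p = 0.00739). The class II histocompatibility genes H2-Aa and H2-Eb1 fell 6.87-fold and 7.54-fold. Ubd, Gbp4 and Igtp, which interferon-gamma induces, had log2 fold changes of -7.22, -3.80 and -3.14. Gzma, which encodes granzyme A of cytotoxic lymphocytes, the chemokine gene Ccl8 and the surface receptor gene Slamf8 had log2 fold changes of -3.16, -3.25 and -5.49. Saline 2 and 3 held 107 and 123 CPM of Ubd against 2.73 to 27.03 CPM in the other saline libraries. Without both libraries the log2 fold changes of Ubd, Slamf8, Jchain, Gbp4, Igtp, Ccl8, H2-Aa and H2-Eb1 were -5.19, -3.42, -3.19, -3.10, -2.25, -2.18, -2.03 and -1.96. That of Ubd was -6.63 without saline 3 and -7.94 without bleomycin 4, that of Slamf8 -4.90 without saline 2, and Ccl8 lost its call without bleomycin 2 (adjusted p = 0.0525).

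The epithelial markers that passed rose for type 1, transitional and type 2 cells and fell for club and secretory cells. Most type 2 and club cell markers did not pass, and no test compared the cell types. Of 15 alveolar type 1 cell markers, 7 rose and 0 fell (9 rose when adjusted over the list alone), with a median log2 fold change of 1.09. Ager went from 687 ± 320 to 1948 ± 260 CPM, and Col4a3, a basement membrane collagen, rose 3.79-fold. Hopx was at 221 ± 110 and 328 ± 227 CPM (adjusted p = 0.406). Of 18 markers of transitional alveolar epithelial cells, an intermediate state between type 2 and type 1 cells, 8 rose and 0 fell (9 adjusted over the list alone; median 0.85). The cornified envelope gene Sprr1a rose from 0.803 ± 0.509 to 15.2 ± 11.95 CPM and Hbegf, a growth factor gene, 3.63-fold, while Krt8 was at 277 ± 103 and 423 ± 79.2 CPM (log2 fold change 0.61, adjusted p = 0.129), and passed without saline 1 and 4 (0.998, adjusted p = 0.0246). Of 16 type 2 cell markers, 2 rose, the surfactant protein gene Sftpb (2.42-fold) and the lipid transporter gene Abca3 (2.22-fold), or 3 when adjusted over the list alone. Sftpc had a log2 fold change of 0.11 ± 0.425 (adjusted p = 0.887), whose sign was negative with a GC correction, and Sftpb lost its call with that correction (adjusted p = 0.0821). Of 16 club and secretory cell markers, 3 fell (3 adjusted over the list alone), Scgb3a1, Reg3g and Muc5b, with log2 fold changes of -3.71, -3.99 and -2.39. Scgb3a1 lost its call without bleomycin 3, 4 or 5, Reg3g without saline 1 or 4 or bleomycin 1, 3, 4 or 5, and Muc5b without saline 1 or 4 or bleomycin 2, 3 or 4 (highest adjusted p 0.065, 0.0749 and 0.0762). The log2 fold change of Reg3g was -5.21 without bleomycin 2. Scgb1a1 made up 11.5% (95% Wilson interval 11.48 to 11.51) and 12.1% (12.13 to 12.16) of all counts in saline 1 and 4, and 1.77% to 8.24% in the other libraries. The 4 lists passed camera with the preset correlation. Without saline 1 and 4, 0 of the 16 club cell markers fell, with a median of -0.33, and the list lost camera (adjusted p = 0.159), whereas 8 fell without saline 2 and 3 (median -1.40). Type 2 markers lost camera without saline 2 and 3 (adjusted p = 0.203). With an estimated correlation the adjusted p was 0.224, 0.0516, 0.529 and 0.551 for type 1, transitional, type 2 and club cell markers.

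Of 31 targets of p53, the transcription factor that DNA damage activates, 8 rose and 0 fell (12 rose when adjusted over the list alone), with a median log2 fold change of 0.50. Beside Cdkn1a, Tnfrsf10b, which encodes a death receptor, rose 4.69-fold, Btg2 1.78-fold and the cytokine gene Gdf15 7.27-fold. Tnfrsf10b had a log2 fold change of 2.23, and 1.59 without bleomycin 1. That of Gdf15 was 2.86, 3.58 without saline 2 and 4.39 without saline 2 and 3, and its call was lost without bleomycin 5 (adjusted p = 0.0564) and without saline 1 and 4 (2.47, adjusted p = 0.0568). The list passed camera and fry (adjusted p = 0.000691), and its adjusted p was 0.0516 with an estimated correlation. Without saline 2 and 3, 13 of the 31 rose, and without saline 1 and 4, 4 did (medians 0.52 and 0.72).

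Of 33 genes of the apoptosis machinery, 1 rose and 9 fell (1 and 11 adjusted over the list alone). The median log2 fold change was -0.32, with an adjusted p of 0.529 by camera with an estimated correlation. On TPM the median was 0.20, where that of all genes moved to 0.44. The largest falls were of Bcl2a1b and Bcl2a1d, near-identical survival genes of leukocytes whose reads cannot be told apart with certainty, and of the survivin gene Birc5. Bcl2a1b lost its call without bleomycin 2, 3 or 5 (highest adjusted p 0.0612), and Birc5 without any 1 of the bleomycin libraries or saline 3 (highest adjusted p 0.0749), as well as without saline 2 and 3 (adjusted p = 0.0508) and with a GC correction (adjusted p = 0.0522). Mcl1, at 626 ± 250 and 577 ± 202 CPM, had an adjusted p of 0.818. Of 44 core autophagy genes, 1 passed the threshold and 0 did when adjusted over the list alone, and the median log2 fold change was -0.02 (camera adjusted p = 0.519) and 0.15 with total-count scaling. The 1 was Atg5, which acts in conjugation at the forming autophagosome, at 45.9 ± 8.55 and 29.3 ± 2.62 CPM (adjusted p = 0.0247). It lost its call without bleomycin 2, 3, 4 or 5 (highest adjusted p 0.0623), without saline 1 and 4 (adjusted p = 0.0678) and with a GC correction (adjusted p = 0.0793). Gabarap was at 355 ± 79.3 and 331 ± 38.8 CPM.

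Of 14 natural killer cell markers, 13 fell (14 adjusted over the list alone), with a median log2 fold change of -2.43. Klrg1, an inhibitory receptor gene, went from 11.98 ± 6.08 to 0.801 ± 0.567 CPM, and the chemokine gene Xcl1 fell from 1.25 ± 0.532 to 0.129 ± 0.141 CPM (log2 fold change -3.14, and -3.86 without bleomycin 3). Xcl1 had few counts, and the filter kept it in 6 of the 11 fits that left out 1 library. Of 16 T cell markers, 11 fell (14 adjusted over the list alone; median -1.94), among them Cd4 (5.17-fold), Cd3d (4.38-fold) and Themis (5.55-fold). Of 18 dendritic cell markers, 8 fell (12 adjusted over the list alone; median -1.80), and Xcr1, a receptor of the cross-presenting subset, went from 17.0 ± 2.40 to 1.45 ± 0.898 CPM. Cd74 had a log2 fold change of -2.22 ± 0.751 (adjusted p = 0.077), -0.75 without saline 2 and 3 (adjusted p = 0.283) and -2.69 without saline 1 and 4, where it passed (adjusted p = 0.0317). The 3 lists passed camera and fry. With an estimated correlation the adjusted p was 0.0516 for natural killer, 0.238 for T and 0.0771 for dendritic cell markers. Without saline 2 and 3, 13 of 13 natural killer, 11 T and 11 dendritic cell markers fell, and without saline 1 and 4, 13 of 14, 13 and 10 did. Of 14 B cell markers, 1 fell (1 adjusted over the list alone).

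Chemokine, interferon-stimulated and recruited macrophage genes had, as lists, their highest means in saline 2 and 3. Of 38 cytokine and chemokine genes, 9 fell and 3 rose (19 and 3 adjusted over the list alone), with a median log2 fold change of -1.62. Cxcl9 had a log2 fold change of -5.93 ± 1.13, Ifng, the interferon-gamma gene, of -5.65 ± 1.10, and Cxcl5 of -4.07 ± 1.01. Ifng was at -6.75 without bleomycin 3 and Cxcl5 at -3.27 without saline 2, and the 3 genes were at -3.98, -3.82 and -1.38 when saline 2 and 3 were left out. Cxcl5 lost its call without any 1 of the bleomycin libraries (highest adjusted p 0.0698) and with a GC correction (adjusted p = 0.0518). Saa3 stood at 5674 and 3566 CPM in saline 2 and 3 and at 22.02 to 270 CPM in the other 9 libraries. Of 32 interferon-stimulated genes, 6 fell (6 adjusted over the list alone; median -0.51), among them the GTPase genes Gbp2, Igtp and Iigp1 with log2 fold changes of -3.62, -3.14 and -2.99. Gbp2 lost its call without bleomycin 2 or 4 (highest adjusted p 0.0528) and Iigp1 without bleomycin 2 (adjusted p = 0.0536). Gbp2 was at -2.91 without saline 3, and Gbp2 and Iigp1 were at -1.92 and -1.76 without saline 2 and 3. Of 23 markers of recruited monocytes and macrophages, 2 fell and 1 rose (9 and 2 adjusted over the list alone; median -1.65). The 2 were Ccr2 and Ms4a4c, with log2 fold changes of -1.80 and -2.40, and C1qa had one of -1.65 ± 0.700 (adjusted p = 0.139). The 3 lists passed camera, and with an estimated correlation the adjusted p was 0.529, 0.557 and 0.557. Without saline 2 and 3 their medians were -0.56, -0.11 and -0.11, and only the cytokine list passed camera (adjusted p = 0.0458). Leaving out saline 1 and 4 instead gave medians of -1.90, -0.79 and -2.03, and 15, 7 and 8 genes fell.

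**Figure D2:**
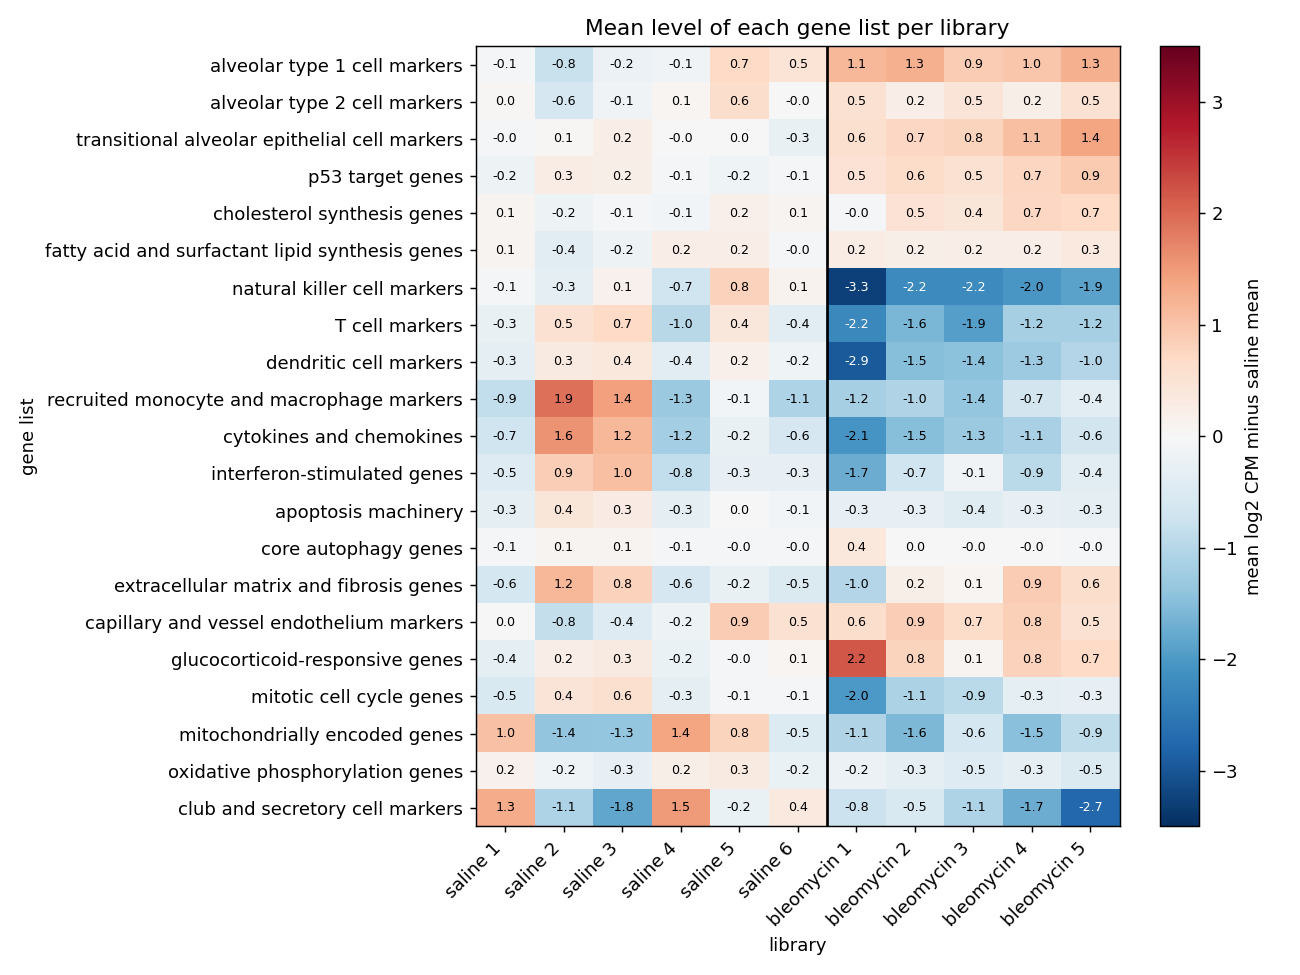
Mean log2 CPM of the members of 21 gene lists (rows) in each library (columns) minus the mean of the saline libraries, in log2 units given in each cell and by colour. Natural killer cell markers lay between -3.28 and -1.88 in the 5 bleomycin libraries and between -0.69 and 0.80 in saline, while recruited macrophage markers reached 1.92 and 1.43 in saline 2 and 3.

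Of 22 cholesterol synthesis genes, 7 rose and 0 fell (8 rose when adjusted over the list alone), with a median log2 fold change of 0.39. Lss, which encodes lanosterol synthase, rose 2.27-fold and Hsd17b7 2.05-fold, while Insig1 was at 51.3 ± 5.34 and 67.2 ± 10.2 CPM (adjusted p = 0.0752, and 0.0305 with a GC correction, where it passed). Of 23 genes of fatty acid and surfactant lipid synthesis, 7 rose (8 adjusted over the list alone, where 1 also fell; median 0.25), with Fasn, the fatty acid synthase gene, up from 109 ± 23.7 to 277 ± 59.1 CPM. Both lists passed camera and fry, and with an estimated correlation the adjusted p was 0.488 and 0.426. Without saline 1 and 4, 3 cholesterol and 4 fatty acid genes rose (medians 0.47 and 0.35). Without saline 2 and 3, 8 and 7 rose (medians 0.39 and 0.14). There 2 fatty acid genes also fell, and that list lost camera (adjusted p = 0.171). Hsd17b7 lost its call without bleomycin 2, 4 or 5 (highest adjusted p 0.0632) and without saline 1 and 4 (adjusted p = 0.0577).

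Of 43 extracellular matrix and fibrosis genes, 2 rose, Ccn1 (2.96-fold) and Thbs1 (2.42-fold), which encode matricellular proteins, and 1 fell, the activin gene Inhba, with the same counts adjusted over the list alone. The median log2 fold change was 0.04 (camera adjusted p = 0.122) and -0.08 without saline 1 and 4, and Sparc had an adjusted p of 0.46. Inhba had a log2 fold change of -3.55, -2.60 without saline 2 and -1.56 without saline 2 and 3, and lost its call without any 1 of the bleomycin libraries (highest adjusted p 0.0681). Leaving out saline 2 and 3, 14 of the 43 rose, the median was 0.73 and the list passed camera (adjusted p = 6.48e-06, and 6.1e-06 with a GC correction as well), while without saline 1 and 4, 2 rose (adjusted p = 0.973). Of 19 endothelial markers, 4 rose (7 adjusted over the list alone; median 0.65), among them Eng 2.15-fold, Gpihbp1 2.27-fold and the von Willebrand factor gene Vwf 2.40-fold. Eng lost its call without bleomycin 2, 4 or 5, Gpihbp1 without saline 1, 3 or 4 or bleomycin 1, 2, 4 or 5, and Vwf without saline 1, 3 or 4 or bleomycin 2, 4 or 5 (highest adjusted p 0.0585, 0.0653 and 0.0799), and 0 endothelial markers rose with a GC correction or without saline 1 and 4. The list's adjusted p was 0.529 with an estimated correlation.

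Of 12 mitochondrially encoded genes, 4 fell (5 adjusted over the list alone; median -1.33), among them mt-Co3, mt-Atp6 and mt-Nd3 with log2 fold changes of -2.24, -2.10 and -1.99. They made up 10.4% (95% Wilson interval 10.41 to 10.44), 12.9% (12.87 to 12.90) and 7.27% (7.26 to 7.29) of counts in saline 1, 4 and 5, and 1.93% to 4.91% in the other 8 libraries. These 3 genes lost their calls without saline 1, 4 or 5 or any 1 of the bleomycin libraries, except that mt-Nd3 kept its call without bleomycin 1 (highest adjusted p 0.0778, 0.0824 and 0.0765). With a GC correction or without saline 1 and 4, 0 of the 12 fell (medians -0.69 and -0.49), and without saline 2 and 3 all 12 did (median -1.78). Cardiac muscle genes, of which 0 passed over all libraries, were high in saline 1, 4 and 6 (means of 1.29, 1.33 and 1.33 above the saline mean on the log2 scale). Of these 12 genes, 9 fell when saline 2 and 3 were left out (median -1.77), and 0 of 11 when saline 1 and 4 were (median -0.48). Of 31 oxidative phosphorylation genes, 7 fell (10 fell and 1 rose when adjusted over the list alone), including Cox7b (2.00-fold) and Ndufa1 (2.01-fold). The list median was -0.30, and 0.21 on TPM, where that of all genes moved to 0.44. Cox7b lost its call without bleomycin 2, 3 or 5, and Ndufa1 without saline 1, 4 or 5 or bleomycin 2, 3, 4 or 5 (highest adjusted p 0.0614 and 0.0748). Leaving out saline 1 and 4, 0 oxidative phosphorylation genes fell (median -0.21), and leaving out saline 2 and 3, 14 did. Of 27 mitotic genes, 4 fell (13 adjusted over the list alone, median -1.02), with the proliferation marker gene Mki67 at 59.1 ± 13.4 and 22.8 ± 10.4 CPM (adjusted p = 0.0154). With a GC correction 1 of the 27 fell, without saline 2 and 3 it was 2 (median -0.71), and without saline 1 and 4 it was 3 (median -1.16). The 3 lists passed camera, and each had an adjusted p of 0.529 with an estimated correlation.

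Of 15 glucocorticoid-responsive genes, 4 rose (6 adjusted over the list alone; median 0.82, adjusted p = 0.529 with an estimated correlation), among them Dusp1, a phosphatase gene, from 102 ± 16.1 to 331 ± 285 CPM. The fit without saline 2 and 3 had 8 glucocorticoid-responsive and 10 immediate early genes that rose, and the fit without saline 1 and 4 had 1 and 2. Bleomycin 1 held 838 CPM of Dusp1 and the other bleomycin libraries 148 to 226 CPM. The log2 fold change of Dusp1 was 1.69, and 0.998 without bleomycin 1, and its call was lost without saline 1 and 4 (adjusted p = 0.0672). In the remaining 17 lists, 4 of 20 immediate early genes and 3 of 21 fibroblast and smooth muscle markers rose, and 4 of 29 DNA replication and 2 of 35 lysosome genes fell (6, 4, 4 and 1 adjusted over the list alone). Of 11 neutrophil markers 1 rose, and of 15 alveolar macrophage markers, 8 eosinophil, basophil and mast cell markers and 36 DNA repair genes 1 each fell (1, 2, 2 and 0 adjusted over the list alone in those directions). Antioxidant genes (2 up, 2 down of 26), endoplasmic reticulum stress genes (2 up, 3 down of 26) and clock genes (1 up, 1 down of 18) moved both ways, with 3 and 3, 2 and 4, and 3 and 2 adjusted over the list alone. No ciliated, erythroid, cardiac, ribosomal protein or sex-linked gene passed over all genes tested, nor did a member of the skeletal muscle, fat, thymus and thyroid list, where 2 fell when adjusted over the list alone. This depended on the saline libraries. When saline 2 and 3 were left out, 15 of 29 ribosomal protein genes (median -0.76), 3 of 17 ciliated, 2 of 11 erythroid and 3 of 5 skeletal muscle, fat, thymus and thyroid genes fell, and without saline 1 and 4, 0 of each did. Immediate early genes (up), fibroblast markers (up) and B cell markers, DNA replication, lysosome, cardiac and ribosomal protein genes (down) passed camera. With an estimated correlation their adjusted p was 0.529, 0.557, 0.570, 0.551, 0.712, 0.605 and 0.551.

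Of the 39 lists, 26 passed camera with the preset correlation (10 up, 16 down) and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry, 8 lists passed, all of them among the 26: type 1, transitional, T, natural killer and dendritic cell markers, p53 targets, and cholesterol and fatty acid synthesis genes. Type 2, fibroblast, recruited macrophage and B cell markers and apoptosis, lysosome, interferon-stimulated, DNA replication and fatty acid synthesis genes lost camera without saline 2 and 3, as did club cell and cardiac genes without saline 1 and 4. Lists that passed in these fits but not over all libraries were the matrix, ciliated (median -0.64) and skeletal muscle, fat, thymus and thyroid lists without saline 2 and 3, and ciliated (median 0.43) and alveolar macrophage markers without saline 1 and 4. In 9 of 100 groupings of the libraries into 5 and 6, the real one included, at least 26 lists passed camera.

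The libraries varied within groups. The first component of log2(FPKM + 1) over 11138 genes (38.7% of variance) set saline 2 and 3, at -60.7 and -53.8, apart from the other 9 libraries, which lay between -1.88 and 34.0. The second (31.8%) held all bleomycin libraries between 23.6 and 29.2 and all saline libraries between -37.6 and -0.725. The third (11.4%) set bleomycin 1, at 45.5, apart. Across genes, which are not independent replicates, log2 fold change correlated with GC content (Spearman's rho 0.396). Genes that rose averaged 54.8% GC and genes that fell 46.4%.

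**Figure D3:**
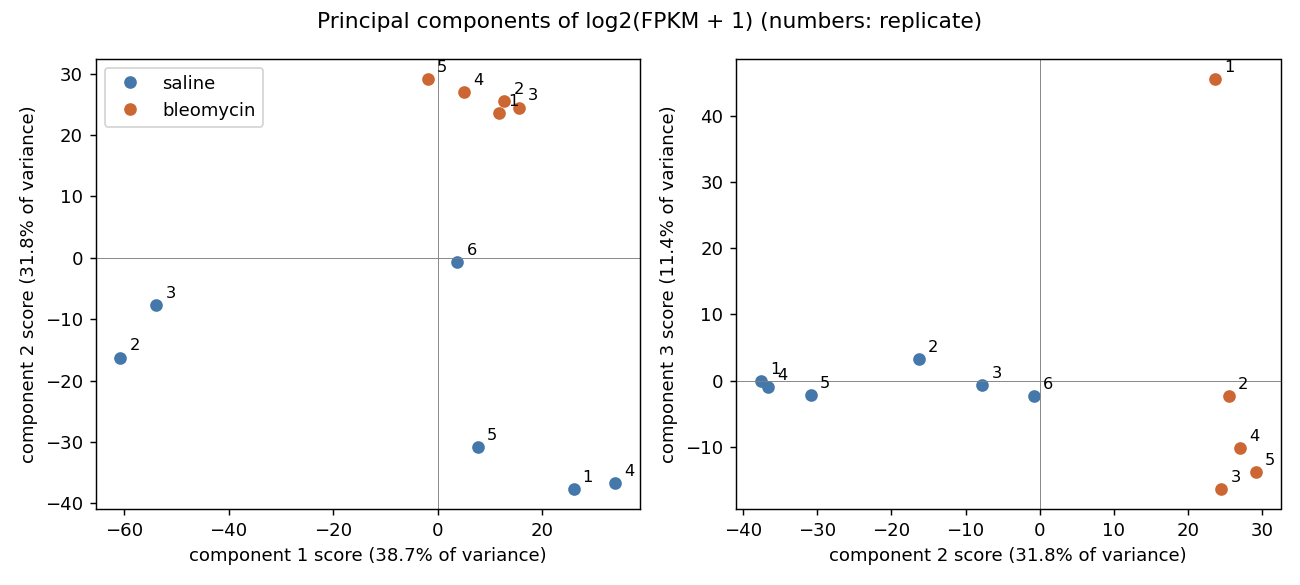
Scores of the saline (blue) and bleomycin (orange) libraries, numbered by replicate, on principal components 1 and 2 (left) and 2 and 3 (right) of log2(FPKM + 1), without units. Saline 2 and 3 stood apart on component 1 and bleomycin 1 on component 3, while component 2 separated the 2 groups.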

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

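The lists described with examples were chosen after the results were seen, and the test on Cook's distance was chosen before its result was. The gap of the highest or lowest library to its neighbour was divided by the range of its group, and 15 of 252 group values lay past Dixon's 95% critical value, where chance alone (about 1 in 20 groups) gives 12.6. Of the 15, 8 were in bleomycin 1.

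Bleomycin 1 was lowest in Ccl8 (gap of 0.776 of the range) and Gzma (0.736), and in the mean level of natural killer (0.748) and dendritic cell markers (0.752), which lay at -3.28 and -2.95 against the saline mean on the log2 scale. It was highest in Dusp1 (0.755), in core autophagy genes (0.825, at 0.36 against -0.05 to 0.02 in the other bleomycin libraries) and in cardiac muscle genes (0.745). The library size implied by its FPKM values was 1.34% above the total of the table (0.951), against -0.0443% to 0.0242% in the other bleomycin libraries. A rule such as DESeq2's Cook's distance could have removed genes before the table was made. It marked 0% of the genes in the table, but also only 0.0138% of unfiltered simulated counts, so this test decided nothing.

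Bleomycin 3 was lowest in Tmem37 (0.723), at 20.7 CPM against 48.9 to 67.8 CPM, in the mean level of apoptosis genes (0.848) and in the correlation of its levels with gene length (0.781). Bleomycin 5 was lowest in Tff2 (0.922), at 0.156 CPM against 1.16 to 1.33 CPM, and highest in fatty acid and surfactant lipid synthesis genes (0.750). Saline 6 was lowest in Thbs1 (0.664), at 137 CPM against 225 to 289 CPM. Saline 5 was highest in globin transcripts (0.780), at 0.532% of counts (95% Wilson interval 0.529 to 0.536) against 0.0832% to 0.182% in the other saline libraries. Bleomycin 4 held 2.13%.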

How the results depend on the processing

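The fits without saline libraries 2 and 3 or 1 and 4, the GC correction and total-count scaling were chosen after the data were seen. Plac8 was lower after bleomycin in every alternative run by edgeR, limma or DESeq2 (log2 fold change -2.13 to -0.47, adjusted p 0.00635 to 0.375). It passed the threshold only with DESeq2 (-1.75, adjusted p = 0.00635), without saline 4 or 6 and, by edgeR, without saline 1 and 4 (-2.13, adjusted p = 0.0237). The exact rank-sum test gave an adjusted p of 0.240 and has no fold change of its own. Between 18 and 28 lists passed camera, against 26 in the main test. No filter and median-ratio factors left the direction and call of Plac8, the other 112 named genes and the 28 lists compared unaltered, although 27 of the 39 lists passed with median-ratio factors. Where no reason is given below, the cause was not tested.

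Leaving out 1 library at a time gave 557 to 2118 genes, 386 to 1057 changed at least 2-fold, 24 to 27 lists, and Plac8 at -1.95 to -1.46. The counts fell most without bleomycin 2 (557), 5 (621), 4 (627) and 3 (765), or saline 1 (863). Values with a main estimate near 0 took either sign: core autophagy -0.059 to 0.016, extracellular matrix -0.074 to 0.42, Mcl1 -0.36 to 0.087 and Sftpc -0.043 to 0.44. A replicate block, although the numbers pair no libraries (correlations -0.19 to 0.01), gave 506 genes, 399 of them at least 2-fold, with Plac8 at -1.65 (p = 0.128).

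A threshold of 0.01 left 247 genes, by construction. The stricter filter tested 5088 genes and gave 732 (266 at least 2-fold), with core autophagy at 0.0052. The exact rank-sum test gave 0 genes, also at 2-fold, against 3299 at an unadjusted p under 0.05, 1496 by edgeR and 2864 by DESeq2. Its smallest p, 0.00433, was reached by 1217 genes where 1254 were needed. DESeq2 gave 1172 genes at least 2-fold.

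The limma fits used FPKM and so differ from the main test by the tool as well. At 2-fold they gave 345 genes with log2(FPKM + 1), 329 with median ratios, 356 with quantiles and 341 with robust variances, but 555 and 580 with pseudocounts of 0.1 and 0.01, 721 on TPM and 1068 with array weights. With pseudocounts of 1, 0.1 and 0.01, core autophagy lay at 0.15, 0.16 and 0.16, Mcl1 at 0.087, 0.088 and 0.088 and Gabarap at 0.10 in each, and robust variances gave 0.15, 0.087 and 0.10. Quantiles gave 0.041, 0.16 and 0.16, and no value for Scgb1a1, which they fix as the top gene. TPM gave 905 genes (851 up, 54 down) and moved the median of all genes to 0.44, against -0.04 in the main test. Under it core autophagy lay at 0.48, oxidative phosphorylation at 0.21, apoptosis at 0.20, lysosome at 0.14, DNA replication at 0.087, Gabarap at 0.43, Mcl1 at 0.42, Ccnb2 at 0.082 and Pcna at 0.041. Array weights, from 0.180 to 10.1 (saline 1), gave 7618 genes (5821 up, 1797 down), against 671 up and 825 down in the main test. They put lysosome at 0.43, recruited macrophages at 0.39, B cells at 0.33, core autophagy at 0.26, interferon-stimulated genes at 0.17, apoptosis at 0.13, DNA replication at 0.11, Mcl1 at 0.52, Ccnb2 at 0.46, C1qa at 0.39, Cd74 at 0.33 and Gabarap at 0.24.

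The fit without saline 2 and 3 called 2778 genes, 1183 at least 2-fold. Saa3 lay at 0.53, Mcl1 at 0.27, lysosome at 0.13 and Sftpc at -0.17. Without saline 1 and 4 there were 876 genes, with core autophagy at 0.072 and extracellular matrix at -0.075. The GC correction gave 946 genes, with core autophagy at 0.057, extracellular matrix at -0.0011 and Sftpc at -0.11. With saline 2 and 3 left out as well, Saa3 lay at 0.55, Mcl1 at 0.21, lysosome at 0.088, core autophagy at 0.072, interferon-stimulated genes at 0.040, Cldn5 at -0.091 and Sftpc at -0.42. Total-count scaling put core autophagy at 0.15, Gabarap at 0.081 and Mcl1 at 0.0066, and moved the median of all genes to 0.14. Depth, 13226339 to 19009284 counts per library, limits what can be said of genes with few counts.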

Other observations

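The genes of this paragraph were chosen after the results were seen, among members of the lists that passed the threshold in all 11 fits leaving out 1 library. The GC correction, and the tests of the calls that ended with it, of a wrong label, of lymph node and of the share of saline 2 and 3 in the fall of natural killer cell markers, were chosen after the patterns were seen. Fosb and Nr4a1, immediate early transcription factor genes, rose 7.53-fold (adjusted p = 0.00891) and 4.24-fold (adjusted p = 0.0189). Bleomycin 1 carried much of this, and without it their log2 fold changes went from 2.91 to 2.25 and from 2.08 to 1.26. The call of the gene Nr4a1 was lost without saline 1 and 4 (adjusted p = 0.0613). Gpx3, which encodes the extracellular glutathione peroxidase, rose from 707 ± 196 to 1889.8 ± 308 CPM (adjusted p = 0.00519). The peroxiredoxin gene Prdx1 fell from 993 ± 261 to 387 ± 12.05 CPM (adjusted p = 0.00512). The stress response genes Chac1 and Ppp1r15a rose 3.09-fold and 2.32-fold (adjusted p = 0.0104 and 0.0151). The clock genes Npas2 and Bhlhe41 had log2 fold changes of 1.62 and -1.06 (adjusted p = 0.00784 and 0.00563). The exact rank-sum test passed none of these 8 genes (adjusted p = 0.0515 for each, where 0 genes passed against 3299 unadjusted, 1496 by edgeR and 2864 by DESeq2), Prdx1 and Bhlhe41 lost their calls on TPM, and Fosb, Nr4a1, Ppp1r15a and Npas2 lost theirs with a block by replicate number.

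With all genes tested, 1496 were called, and 1 of 100 splits of the libraries into 5 and 6, the real one, gave as many (highest of the others 305). For genes changed at least 2-fold it was likewise 1 of 100 (778, highest other 283). None of the other splits drawn reached either count, and 1 of 100 is the smallest share that 100 splits can show. Splits that mix the groups carry the difference between the groups as spread, which can lower their counts. The split with 305 genes set saline 4 and the bleomycin libraries against the other saline libraries. For lists past camera, 9 of 100 splits gave at least 26 (highest other 29), so chance cannot be excluded for that count.

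Genes that rose were richer in GC than genes that fell, with a correlation of 0.396 between GC content and log2 fold change. A GC trend across libraries was not the whole cause of the calls. After correction, 759 of the 1496 genes (50.7%, 95% interval 48.2 to 53.3) were called in the same direction. This alone left the bound of 50% undecided. Natural killer cell markers stayed low, as given below, and 13 of 14 still fell. Oxidative phosphorylation genes kept a median of -0.36 (-0.51 to -0.21), though 3 of 31 fell, against 7 before. Their median GC content, 48.8%, lay near the mean of the genes tested (50.2%), so this list tests the trend weakly. Intervals in this and the following paragraphs are over genes, whose levels are correlated, and leave out the spread between libraries. The 737 genes that lost their call went from a median of 0.84 (quartiles 0.65 and 1.12) to 0.55 (0.37 and 0.87) in the direction of the call. Their median SE was 0.21 before and after. The estimates thus shrank at the median, which does not show why each call ended. The Benjamini-Hochberg cutoff was also lower, with 946 genes called against 1496. The 737 genes kept 69.1% of their log2 fold change (67.4 to 70.7). Trend and treatment cannot be told apart for them, since the GC correlation was -0.451 to 0.0706 in saline and 0.157 to 0.403 in bleomycin libraries.

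Interferon-induced, chemokine and macrophage genes were high in saline 2 and 3, and the design names no group that would separate these libraries, so no biological explanation was tested. A wrong label was left open by transitional epithelial markers, which in the higher of the 2 lay at -0.32 (-0.84 to 0.45) relative to the lowest bleomycin library. Natural killer cell markers, tested after that, lay 1.55 (1.07 to 1.95) above the highest bleomycin library. Their fall was known by then, with 11 of 14 lower in FPKM in all bleomycin than in all saline libraries. That result was thus settled beforehand and is no independent evidence against a wrong label. Lymph node carried along at dissection as the only source was argued against by T cell markers. They rose less than macrophage markers (log2 difference -0.72, interval -1.24 to -0.21). A part from lymph node stays open. B cell markers, which were not in this test, had a median log2 fold change of -0.80, and -0.27 without saline 2 and 3. Inflammation of these lungs for another reason may be the source, which was not tested.

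Of the markers tested, 13 of 14 of natural killer, 11 of 16 of T and 8 of 18 of dendritic cells fell with bleomycin. A GC trend was argued against by the median of natural killer cell markers after correction, -2.15 (-2.91 to -1.98). Lymph node carried along in saline libraries was left undecided. The median of B cell markers lay 1.63 (1.09 to 2.01) above that of natural killer cell markers. This comparison was chosen after the falls were seen, and it did not include T and dendritic cell markers. Saline 2 and 3 did not carry the fall, since 100% of the natural killer cell markers tested (77.2 to 100) passed without them. A loss of these cells after bleomycin was not tested and stays open.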
